A study of Triticum aestivum with 6 samples.

How the data were processed

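Embryos were taken from mature seeds of the bread wheat (Triticum aestivum) cultivar AC Domain after 48 h of imbibition, that is, after the dry seeds had taken up water. The mother plants had grown at 22 °C by day and 18 °C by night, with 16 h of light and 8 h of dark, and were moved at flowering to 13 °C or 28 °C, where the seeds developed until harvest. Total RNA was turned into biotin-labelled cRNA and hybridised to the Affymetrix wheat GeneChip, a 1-colour array of short probes grouped into probe sets. The labels give 3 biological replicates per temperature, 6 arrays in all, and do not say whether these came from separate plants, chambers or seed lots. All p-values therefore measure the spread between these samples, which may be partly technical. No scan date, array batch or other batch was named in the sources used here, so no batch could be tested.

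The deposited values are log2 probe set values made by the authors with RMA, per the submitters' processing notes. RMA subtracts background, makes the probe intensities of all arrays follow the same distribution by quantile normalization, and summarises the probes of each set on a log2 scale. The RMA version, the software and which arrays were normalized together are not given in the sources used here. Because quantile normalization makes the distributions equal, a change of total mRNA per embryo cannot be read from these values, and a count of higher and lower probe sets is relative to the bulk of the array. The scanner files were not used here. RMA values carry no detection call. As a guide to background, the highest mean among the 23 control probe sets for trp and Tag, transcripts that were not spiked in, was 4.71, and 54.6% of the tested probe sets had a mean above it. The number of arrays limits the precision of every value.

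Of the 61290 probe sets in the table, 111 Affymetrix control probe sets were left out of the tests and 61179 were tested. The platform's annotation table, which is old, paired 1273 tested probe sets with 1 gene, for 771 genes in all. It paired 0 probe sets with several genes and left 59906 unnamed here. The gene identifiers of 1272 probe sets were matched to the RefSeq gene table of the wheat assembly IWGSC CS RefSeq v2.1, which was used for names only. The array names no genome build, so no positions are given. An informative name, meaning a symbol or a synonym other than a bare locus number, was found for 200 probe sets of 102 genes. The tables hold no gene titles, so the gene lists were matched on symbols and synonyms. Names in the text are those symbols or synonyms, and many are old.

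Differences are 13 °C minus 28 °C on the log2 scale, so that a positive value means higher in embryos of seeds developed at 13 °C. The test was limma (version 3.58.1, in R 4.3.3): lmFit and eBayes with the default prior on all 6 arrays, no covariate, two-sided, with Benjamini-Hochberg adjustment over the 61179 probe sets and a threshold of 0.05. A further count took probe sets that also differed at least 2-fold. For gene lists, limma's camera with a preset correlation of 0.01 compared the members with all other tested probe sets, adjusted over the lists tested. The estimated correlation and the fry rotation test were run beside it. A list needed 5 member probe sets to be tested. Alternatives that left out members still tested lists cut below this size, such as histones with 3 probe sets and LEA proteins with 4. Control probe sets were compared by exact two-sided permutation tests of 3 arrays against 3, which cannot give a p below 0.1. Tables and exact tests used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

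The lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. There were 26 lists: 6 had at least 5 probe sets, 8 had between 1 and 4, and 12 had none. Those with none include abscisic acid synthesis and signalling, gibberellin signalling, cell cycle and DNA replication, cold response and storage globulins, which were not analysed here. The naming rule took the 10 higher and 10 lower named genes with the largest difference among probe sets past the threshold whose groups did not overlap, with 1 probe set per gene. It added up to 4 members per fixed list (those past the threshold with the largest difference or, where none passed, the 2 with the smallest p) and all members of the gibberellin synthesis and dormancy lists. It also allowed the 2 most changed unnamed probe sets per direction, which the text describes without their identifiers. A planned enrichment of annotation terms was not run, since no table of terms was used here. Another 5 lists were written after the gene names, but not their values, had been seen: histones H2A and H2B, methyl transfer enzymes, sugar phosphate and fructan enzymes, translation, and grain proteins and inhibitors.

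The fit was tested on simulated data for 61179 probe sets, with the real means and with spreads drawn from the prior that limma fitted. Errors were normal and independent, so the simulation follows the model that the test assumes. Correlation between probe sets and uneven arrays were not simulated, so the shares below do not show the error rate in the real data. With 20000 probe sets changed, 85.5% of those with a log2 change of 0.5, 99.2% of those with a change of 1 and 100% of those with a change of 2 were called with the right sign, and 3.39% of the calls were false. With 200 changed, the shares were 2.99%, 82.1% and 100%, and 5.38% of the calls were false. Alternatives covered a replicate block, other normalizations, filters on dim probe sets, other variance priors, array weights, removal of probe sets that can match several transcripts (suffixes _s_at, _x_at and _a_at), other thresholds and leaving out each array in turn. After the control probe sets had been seen, scaling each array to its hybridisation or poly-A controls, leaving out 13 °C arrays 1 and 2 together, and taking the rbcl probe sets out of the photosynthesis list were added. No pair of arrays was a duplicate: between 1589 and 2426 probe sets had exactly equal values in each pair, whether the arrays were of the same or of different groups.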

Results

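The series measured transcript levels in wheat embryos 48 h after the start of imbibition, with seeds that had developed at 13 °C or at 28 °C and 3 arrays per temperature. The comparison addresses how gene expression in the imbibed embryo differs with the temperature of seed development. Correlations between arrays of the same temperature were 0.993 to 0.997, and between temperatures 0.953 to 0.964, across probe sets. The first principal component held 86.8% of the variance and separated the temperatures. Array medians lay between 4.99 and 5.04 on the log2 scale.

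Embryos of seeds developed at 13 °C had far lower signals for histones H2A and H2B, lower beta-tubulin signals and higher signals for Em, a small hydrophilic protein of late embryogenesis. Among named genes, GLU1A (LOC780595), a beta-glucosidase, fell to 4.84 ± 0.41 (SD, n = 3) against 11.50 ± 0.42 at 28 °C, a difference of -6.65 ± 0.24 (SE; adjusted p = 2.6e-07). The largest rise was in EM (LOC543497), at 13.11 ± 0.30 against 10.47 ± 0.34, a difference of 2.64 ± 0.19 (adjusted p = 1.1e-05). Over all tested probe sets, 20517 (33.5%) passed the threshold, 11304 higher and 9213 lower at 13 °C. At least 2-fold differences were found for 5685, of which 2249 were higher and 3436 lower. Large differences lay mostly on the lower side: 31 probe sets were higher and 419 lower by at least 8-fold, and 1 was higher and 81 lower by at least 32-fold. All arrays of one temperature lay above all arrays of the other for 27073 probe sets (44.3%), where chance gives 10%.

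The balance of higher and lower calls depended on the scaling. With the deposited values 55.1% of the calls were higher at 13 °C. With each array scaled to its hybridisation controls, which lowers the median difference by 0.63, 12469 probe sets passed and 5.25% of them were higher, 654 against 11815 lower. With scaling to the poly-A controls, which shifts the median difference by -0.46, 3002 passed and 6.63% were higher. The size of both shifts depends on 13 °C array 1, without which the controls differed by 0.36 and 0.060. The hybridisation controls also differed among themselves, from 0.20 for the brightest to 0.84 for the dimmest, so a single shift is a rough correction. Differences below are those of the deposited values, whose median difference over all probe sets was 0.062. Among the 200 named probe sets, 30 were higher, 56 were lower and 114 did not pass.

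**Figure D1:**
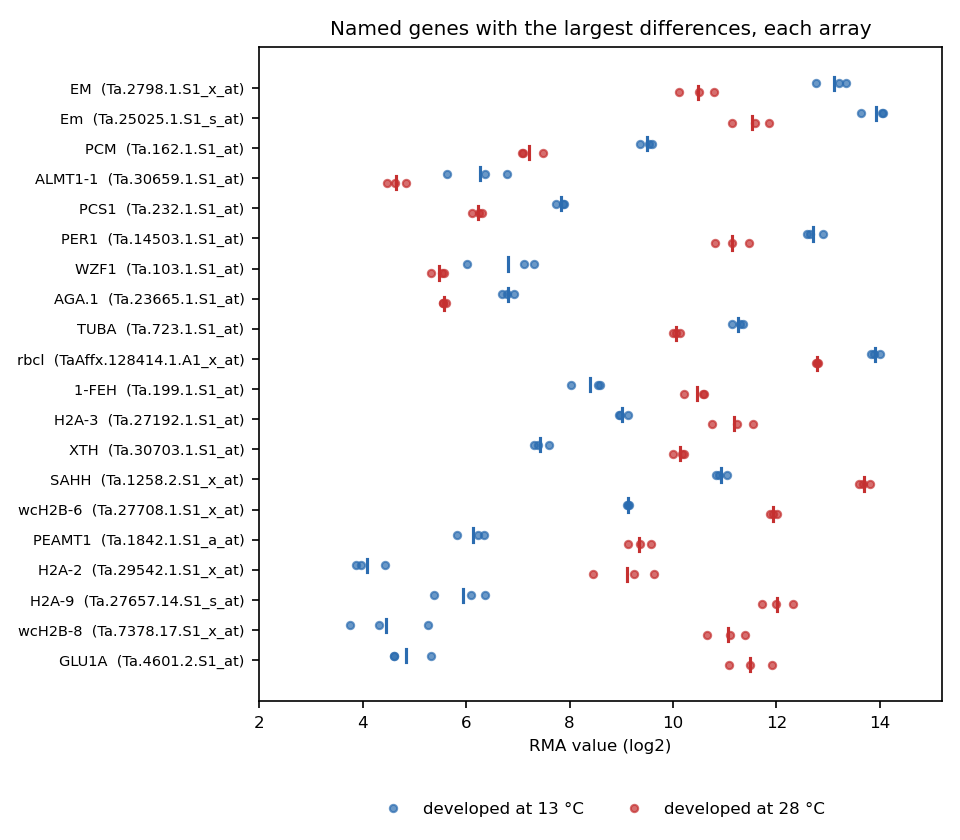
RMA values (log2, horizontal axis) of the 10 higher and 10 lower named genes with the largest differences; each point is an array (3 per temperature, blue 13 °C, red 28 °C) and each vertical bar a group mean. The groups do not overlap for any of the 20, and those of GLU1A lie at 4.84 and 11.50.

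Histones, the proteins that package DNA, showed the largest shift of any fixed list. Of 9 probe sets of 3 H2A genes, 8 fell, 0 rose and 1 did not pass, with a mean difference of -4.48 and a median of -5.33. The count adjusted over the list alone was again 8 lower and 0 higher. H2A-9 (LOC732714) was at 5.94 ± 0.51 (SD, n = 3) at 13 °C against 12.01 ± 0.31 at 28 °C on its most changed probe set (difference -6.07 ± 0.25 SE, adjusted p = 4.2e-07), and its 3 next most changed probe sets differed by -6.02, -5.45 and -5.44, the last of them at 4.26 at 13 °C, below the highest unspiked control at 4.71. H2A-2 fell by 5.02 to 4.09 ± 0.30, also below that control, so both levels at 13 °C were at background; with 13 °C set to the control's level, the differences were -4.99 and -4.41. H2A-3 fell by 2.16 on 1 probe set, while its other probe set differed by 0.18 and did not pass. The name rule of the list did not take in the H2B genes, and wcH2B-8 (LOC543184) and wcH2B-6 (LOC543183) entered as single genes. All 7 probe sets of wcH2B-8 fell, with differences from -1.88 ± 0.13 (8.65 ± 0.19 against 10.53 ± 0.18) to -6.61 ± 0.34, the latter at 4.45 at 13 °C and so -6.35 when counted from the highest unspiked control, and wcH2B-6 fell on both of its probe sets (-2.80 ± 0.08 and -2.77 ± 0.13). The list shift had an adjusted p = 2.3e-09 in camera with the preset correlation, and adjusted p = 0.21 with an estimated correlation. Many of these probe sets carry a suffix for possible cross-hybridisation, so single histone genes of the family cannot be separated firmly.

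LEA proteins and dehydrins, hydrophilic proteins that accumulate as seeds dry, were higher at 13 °C mainly through Em. Of 10 probe sets of 5 genes, 7 rose, 1 fell and 2 did not pass, with a mean difference of 1.47. Adjusted over the list alone, 9 were higher and 1 lower. All 5 probe sets of the Em genes rose, with a mean difference of 2.39, and stayed past the threshold under both control scalings. The rises outside Em, in LEA1 (0.87) and 1 probe set of Rab15 (0.90), did not pass under either, at 0.24 and 0.28 with the hybridisation controls and 0.41 and 0.45 with the poly-A controls. Rab15 passed with 13 °C array 1 left out but not with any other array left out, at 0.67 to 1.03. Em/EMH2 was at 13.92 ± 0.24 (SD, n = 3) against 11.52 ± 0.36 on its most changed probe set, a difference of 2.39 ± 0.19 (adjusted p = 1.6e-05), and the next probe sets of Em/EMH2 and EM differed by 2.35 and 2.29. The member that fell passed the test at a level below the unspiked control maximum in both groups: 7 of the 8 members past the threshold were above it. In camera the list had an adjusted p = 0.00074 with the preset correlation and adjusted p = 0.47 with an estimated correlation. The call was also lost with 1 probe set per gene, at a mean difference of 1.196, and without the cross-hybridising suffixes, at 0.83.

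Tubulin, the subunit of microtubules, made up the whole cytoskeleton list, in which 8 of 10 probe sets fell, 1 rose and 1 did not pass (mean difference -0.71). With p adjusted over the list alone, 9 were lower and 1 higher. Of the 8 beta-tubulin probe sets 7 fell, among them tubb1 (-1.89 ± 0.08 SE, from 13.08 ± 0.03 to 11.20 ± 0.04, SD, n = 3), tubb3 (-1.36 ± 0.09) and Tubb5 (-1.17 ± 0.09, and -0.56 to -1.10 on its other 3 probe sets). The probe sets of alpha-tubulin TUBA disagreed: the larger difference was 1.201 ± 0.09 and the other was -0.50, both past the threshold. The rise of TUBA did not pass with scaling to either set of controls, at 0.57 with the hybridisation controls. With poly-A scaling 3 of the 10 probe sets fell, 0 rose and 7 did not pass, at a larger mean difference of -1.16, since the SE of each difference grew to 0.54. The list had an adjusted p = 1.6e-05 in camera with the preset correlation and adjusted p = 0.21 with an estimated correlation.

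**Figure D2:**
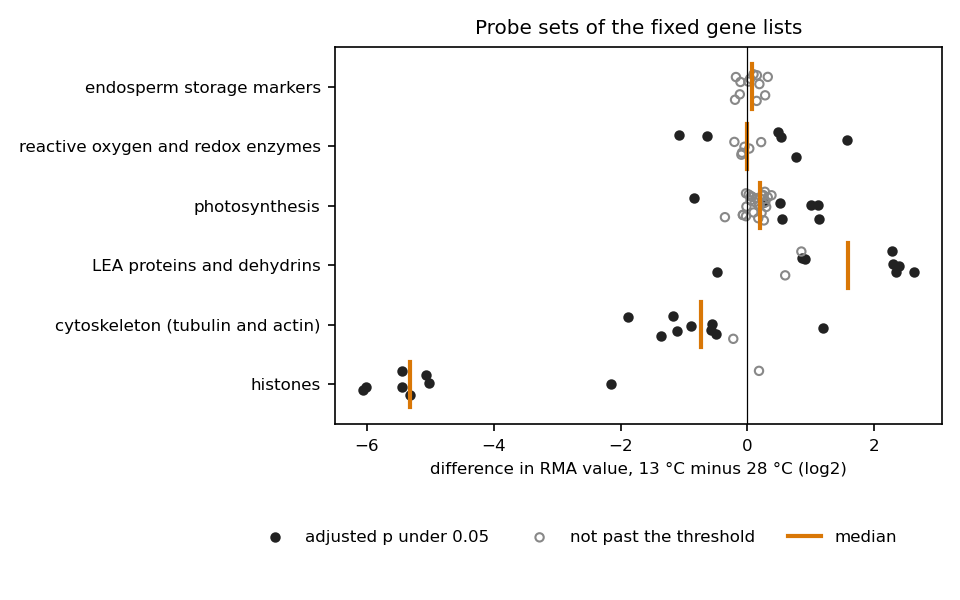
Differences between temperatures (log2, 13 °C minus 28 °C, horizontal axis) of each probe set in the 6 tested lists; filled points passed the threshold, open points did not, and orange bars are medians. Histone probe sets centre on -5.33 and LEA probe sets on 1.59; the photosynthesis, redox and endosperm lists lie near 0, and their mean differences turn negative with scaling to either set of control probe sets.

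Other named genes fell by at least 4-fold. PEAMT1, phosphoethanolamine N-methyltransferase of choline synthesis, was at 6.14 ± 0.27 (SD, n = 3) against 9.35 ± 0.22, a difference of -3.22 ± 0.16 (SE; adjusted p = 1.1e-06). SAHH, S-adenosylhomocysteine hydrolase, which removes the product of methylation reactions, fell by 2.77 to 10.92 ± 0.12, and by 2.37 on its other probe set. XTH, a xyloglucan endotransglucosylase that remodels cell walls and the single member of the cell wall loosening list, differed by -2.69 ± 0.11 (7.44 ± 0.15 against 10.13 ± 0.11). 1-FEH, a fructan exohydrolase, differed by -2.07 ± 0.16. GLU1A was close to the unspiked control maximum at 13 °C, where a lower level could not be resolved.

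Among the genes that rose, PIMT, a methyltransferase that repairs aged aspartyl residues in proteins, was at 9.50 ± 0.12 (SD, n = 3) against 7.22 ± 0.24, a difference of 2.27 ± 0.13 (SE; adjusted p = 2.7e-06). ALMT1, a malate transporter activated by aluminium, differed by 1.62 ± 0.25, or 1.56 counted from the highest unspiked control, since its 4.64 at 28 °C was below that level. PCS1, phytochelatin synthase, differed by 1.62 ± 0.09. WZF1, a zinc finger protein, differed by 1.34 ± 0.29 and AGA.1 by 1.23 ± 0.09; the other AGA.1 probe set, below the highest unspiked control in both groups, differed by -0.18 and did not pass. With scaling to the hybridisation controls WZF1 and AGA.1 no longer passed, at 0.71 and 0.60. Under poly-A scaling ALMT1 and PCS1 did not pass either, at 1.17 and 1.16.

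Gibberellin synthesis was represented by 4 probe sets of 3 gibberellin 20-oxidase genes, of which 1 passed. Ta20ox1A fell by 0.46 ± 0.10 (SE; 4.89 ± 0.05 against 5.34 ± 0.14, SD, n = 3, adjusted p = 0.0058). Ta20ox1B differed by -0.35 (adjusted p = 0.060), or -0.14 counted from the highest unspiked control, since its 4.49 at 13 °C was below that level, and the 2 probe sets of Ta20ox1D by 0.22 and 0.18 (adjusted p = 0.18 and 0.29), values that turn negative under both control scalings. Counts adjusted over the list alone were 0 higher and 2 lower. The dormancy list held PER1, whose synonyms do not settle whether it is a peroxidase or the peroxiredoxin of that name. Its probe sets disagreed, with 1.57 ± 0.16 (adjusted p = 7.5e-05) on the bright probe set and -0.094 on the other, which did not pass; 1 was higher and 0 lower when adjusted over the list alone. The single member of the germination hydrolase list, amy1/BMY1, named after both amylases, differed by -0.997 (adjusted p = 0.0033), with both groups below the unspiked control maximum. As single members, amy1/BMY1 and XTH were also lower when adjusted over the list alone.

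Photosynthesis genes gave no shift past the threshold. Of 33 probe sets, 28 carried the name rbcl, the large subunit of Rubisco, and 6 rose, 1 fell and 26 did not pass; 8 of the 33 were above the unspiked control maximum in either group. The bright rbcl probe sets differed by 1.12 ± 0.09 (SE; 13.91 ± 0.09 against 12.78 ± 0.02, SD, n = 3) and 0.997 ± 0.087, and neither passed under either control scaling. The other 4 rbcl probe sets that passed were below the unspiked control maximum in both groups, so that 3 of the 7 members past the threshold were above it. PsbP, of the oxygen-evolving complex, fell by 0.84 ± 0.15 on 1 probe set and differed by -0.020 on the other, which did not pass (4.92 against 4.94). Their mean difference was 0.21 (adjusted p = 0.058 in camera), turning to -0.41 with hybridisation control scaling and to -0.071 without rbcl. Adjusted over the list alone, 4 were higher and 1 lower.

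Redox enzymes went both ways, with 4 of 12 probe sets higher, 2 lower and 6 not past, and the same counts adjusted over the list alone. The mean difference was 0.12 and the median -0.0068 (adjusted p = 0.95), and both scalings to control probe sets turned the mean negative. GSTZ1, a zeta class glutathione transferase, differed by -1.07 ± 0.10 and -0.64 ± 0.13 (SE, n = 3), and by -0.084 on its remaining probe set, which did not pass (6.33 against 6.41). Of 4 probe sets of Prx1, 3 rose and 1 did not pass (-0.045). One of the brighter rose by 0.53 ± 0.08 (adjusted p = 0.00085), a call kept with any single array left out, and another by 0.48 ± 0.14 (adjusted p = 0.029), lost without 13 °C array 2 (0.40) or 3 (0.52) or 28 °C array 2 (0.37) or 3 (0.44). The dimmest of the 3, at 4.96 against 4.19 at 28 °C, where it was below the highest unspiked control, differed by 0.77 ± 0.20 (adjusted p = 0.015), or 0.26 counted from that control, a call that was lost without 13 °C array 1 (0.70), without 28 °C array 2 (0.73) or without 28 °C array 3 (0.72). None of the Prx1 probe sets passed with scaling to either set of controls.

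Endosperm markers, fixed to detect starchy tissue attached to the embryos, did not differ past the threshold on any of 12 probe sets, over all probe sets or adjusted over the list alone, and 3 of the 12 were above the unspiked control maximum. The mean difference was 0.054 (adjusted p = 0.95), negative with both control scalings, and the smallest p belonged to gliadins Gli-8 (0.19) and gamma-2 (0.28). Ribosomal proteins RPL9 (-0.39, adjusted p = 0.051) and RPS29 (0.18 and -0.086), the small heat shock protein hsp16.9A (0.11), the defence genes wci (0.27) and PR5 (0.017) and the ADP-glucose pyrophosphorylase small subunit AGP-S (0.12) did not pass. For these 4 small lists the counts adjusted over the list alone were 0 higher and 0 lower.

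Unnamed probe sets held the largest measured differences, most of them against a level below the highest unspiked control (4.71), where their size and order are uncertain. The most increased, paired with locus LOC543264, which has no informative name, was at 10.10 ± 0.82 (SD, n = 3) against 4.58 ± 0.45, a difference of 5.52 ± 0.37 (SE; 5.39 counted from that control), and the next, paired with no gene, differed by 4.16 ± 0.31. The most decreased, also paired with no gene, was at 3.08 ± 0.28 against 11.34 ± 0.06, a difference of -8.26 ± 0.14 (-6.63 counted from that control), and the next differed by -7.56 ± 0.22 (-7.36), from 12.07 to 4.51, and belongs to the probe set cluster that holds wcH2B-8.

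Control probe sets moved with the temperatures as well. Hybridisation controls are meant to be spiked in at fixed amounts, but the sources used here do not say whether the amounts or the RNA input were equal. They averaged 11.53 ± 0.51 (SD, n = 3) at 13 °C and 10.90 ± 0.13 at 28 °C (difference 0.63, exact permutation p = 0.1, the smallest possible). The single controls disagreed: bioB differed by 0.84 and bioC by 0.78 with groups apart. The brighter bioD (0.58, exact p = 0.2) and cre (0.20, exact p = 0.3) overlapped. A single shift of 0.63 therefore does not describe all signal levels. Poly-A controls differed by 0.46 (exact p = 0.5), and 13 °C array 2 was the lowest of the 6 at 7.82. Without 13 °C array 1 the hybridisation controls differed by 0.36 and the poly-A controls by 0.060, and without 13 °C array 2 the poly-A controls differed by 0.93. The gap between 3-prime and 5-prime probe sets, a sign of RNA length, was wider at 13 °C by 0.84 for sucrose synthase and by 0.90 for glucose-6-phosphate dehydrogenase (exact p = 0.1 each). Of 7 wheat transcripts with such a gap, EF1a (0.54) and GAPDH (0.43) also had higher 3-prime minus 5-prime values with groups apart (exact p = 0.1 each). For GAPDH that value was negative at both temperatures (-1.88 at 13 °C, -2.32 at 28 °C), so its gap was not wider. CYP86 had a lower value (-1.58, exact p = 0.1), and ubiquitin (-0.071) and actin (-0.14) overlapped. The EF1a 5-prime probe set at 13 °C and the GAPDH and actin 3-prime probe sets at both temperatures were below the highest unspiked control, so these 3 gaps are limited by background. The gap was widest on 13 °C array 2 for sucrose synthase and glucose-6-phosphate dehydrogenase, and without this array that of sucrose synthase differed by 0.50. The probe set for 18S rRNA was higher by 0.43, less than either control shift (0.63 and 0.46), so its sign turns with both scalings. These differences ran alongside the histone and tubulin falls and the Em rises. With 13 °C arrays 1 and 2 left out together, 14531 probe sets passed, 7784 higher and 6747 lower, and 5642 differed at least 2-fold. Ta20ox1A (-0.43 ± 0.14 SE), PsbP (-0.90 ± 0.23) and amy1/BMY1 (-0.93 ± 0.37) then no longer passed, with differences close to those of all arrays and larger SEs. Calls were also lost for the less changed GSTZ1 probe set (-0.43 ± 0.10), the dim Prx1 probe set (0.28 ± 0.15) and the Prx1 probe set at 0.48 (0.41 ± 0.24). With poly-A scaling, where every SE is 0.54, the calls of Ta20ox1A (-0.91), PsbP (-1.29), amy1/BMY1 (-1.45), PER1 (1.12) and both GSTZ1 probe sets (-1.10 and -1.53) were lost.

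**Figure D3:**
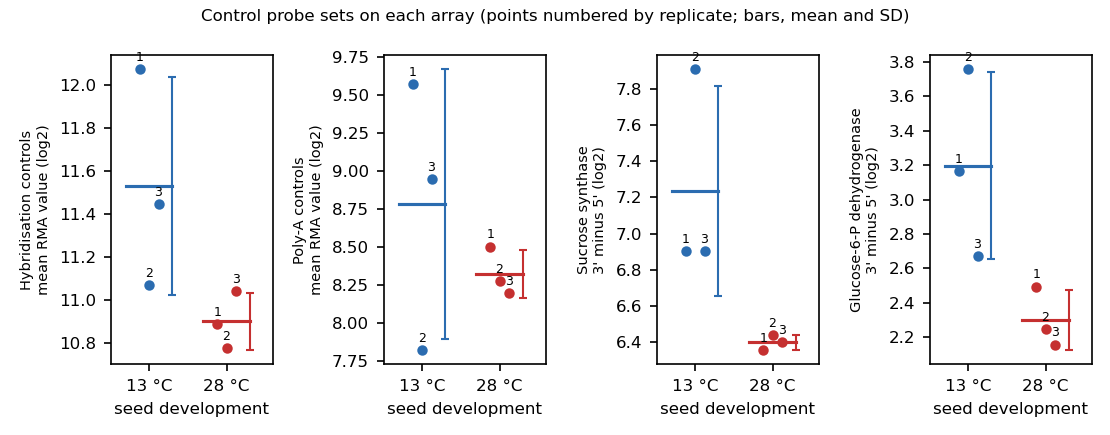
Mean RMA value (log2) of the hybridisation and poly-A controls and 3-prime minus 5-prime gaps (log2) of 2 wheat transcripts for each array (points, numbered by replicate; bars are mean and SD, n = 3; axes do not start at 0). All 13 °C arrays lie above all 28 °C arrays for the hybridisation controls (11.53 against 10.90) and both gaps, but not for the poly-A controls.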

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

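Scaling to the control probe sets, leaving out 13 °C arrays 1 and 2 together and taking rbcl out of the photosynthesis list were chosen after seeing the data. The histone list kept its direction under all alternatives and its side of the threshold under all but the estimated correlation, with a range of -4.66 to -4.33 when single arrays were left out. The count of changed probe sets ranged from 16474 to 19571 with 1 array left out, and was 14531 with 13 °C arrays 1 and 2 left out, where the lone 13 °C array was assumed to vary like the others. Scaling to hybridisation controls gave 12469 changed (654 higher), and 9228 at least 2-fold (482 higher, 8746 lower). Poly-A scaling gave 3002 (199 higher, 2803 lower), all at least 2-fold. Both scalings subtract an array's control value, centred on the mean of the arrays, from every probe set, so that its spread enters every test. Unadjusted p with a 2-fold limit gave 5690 (2249 higher, 3441 lower). Without the suffixes _s_at, _x_at and _a_at, where fewer probe sets were tested, 5763 were lower, and 3687 differed at least 2-fold (2104 lower).

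With the estimated correlation the LEA (1.47), cytoskeleton (-0.71) and histone (-4.48) lists no longer passed. All of these lists passed in fry, which does not compare a list with other genes (adjusted p = 0.010 for LEA and 0.00015 each for cytoskeleton and histones). LEA lost its call with 1 probe set per gene (1.196, adjusted p = 0.070) and without the suffixes (0.83, adjusted p = 0.50), where fewer members were tested. Photosynthesis passed in fry (0.21, adjusted p = 0.010), which does not compare the list with other genes, ranged from 0.17 to 0.25 with single arrays left out, passing without 13 °C array 3 (0.25) or 28 °C array 3 (0.23), and turned negative without rbcl (-0.071) and with hybridisation (-0.41) and poly-A (-0.24) scaling. Endosperm turned negative with 1 probe set per gene (-0.038), with the scalings (-0.57 and -0.40) and with 13 °C arrays 1 and 2 left out (-0.013), and redox with the scalings (-0.51 and -0.33). The means follow the scaling by construction; the cause of the other changes was not tested.

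Over all probe sets the replicate numbers showed no pairing of the arrays. The deviations of same-numbered arrays correlated at 0.044, 0.012 and 0.019, and each 13 °C array correlated best with a 28 °C array of another number (0.059, 0.050 and 0.093). A fit with the replicate number as a block gave 20226 changed probe sets (5690 at least 2-fold), called RPL9, Ta20ox1B and 2 more Rab15 probe sets in addition, and left 5 photosynthesis probe sets higher instead of 6. In the LEA list 9 probe sets were then higher instead of 7 (adjusted p = 2.2e-05 in camera with the preset correlation). Pairing in part of the genes is therefore not excluded. Over 48 named probe sets, of which 36 passed with the deposited values, 928 values under alternatives gave 875 on the same side of the threshold. Another 34 lost the call, 19 gained it and 0 reversed it. Without the 2 control scalings 803 stayed on the same side, 12 lost the call and 17 gained it, so most losses came from the scalings. Many of these probe sets were named for their large differences and many alternatives are alike, so these shares overstate stability. Low signal limits the differences of genes near 4.71, the highest unspiked control.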

Other observations

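Named genes outside the fixed lists and the naming rule, chosen after their values were seen, add further groups. The fructan exohydrolase 6-FEH fell on 2 of 3 probe sets (-2.06, at 4.08 and so at background at 13 °C, and -1.83; 0.027 on the other, not past). Profilin, which binds actin monomers, differed by -1.42 and -1.14, the xylanase inhibitor XIP-I by -1.23 and -1.21, and the plasma membrane proton pump ha1 by -0.62, -0.59 and -0.51. Caffeate O-methyltransferase COMT1 differed by -1.27, adenine phosphoribosyltransferase APT1 by -0.89 and adenylosuccinate synthetase AdSS by -0.70. Higher at 13 °C were GAPN, a non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase (0.93), and wheat germ agglutinin WGA2 (0.80). Scaling to the hybridisation controls lowers each of these differences by 0.63 and poly-A scaling by 0.46, and the SE becomes 0.33 and 0.54. GAPN (0.30 and 0.48) and WGA2 (0.17 and 0.34) passed under neither, and under poly-A scaling APT1 (-1.34), AdSS (-1.16), the less changed profilin probe set (-1.59) and ha1 (-1.07, -1.05 and -0.96) did not pass.

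Among the lists added after the gene names were seen, 17 of 18 H2A and H2B probe sets of 5 genes were lower (mean -4.16). In camera the adjusted p was 4.6e-19 with the preset correlation, 5.5e-07 with 1 probe set per gene and 0.11 with an estimated correlation. This list takes in the fixed histone list, so it is not separate evidence. Of 5 methyl transfer probe sets, 4 were lower and 1 was higher (-1.47). Their adjusted p in camera was 0.0021 with the preset correlation and 0.11 with an estimated correlation. Translation (mean -0.14, adjusted p = 0.21), sugar phosphate and fructan enzymes (-0.33, adjusted p = 0.18) and grain proteins and inhibitors (0.042, adjusted p = 0.94) did not pass in camera. In fry, which does not compare a list with other genes, translation (adjusted p = 5.3e-05) and sugar phosphate and fructan enzymes (adjusted p = 0.0033) passed. In the probe set cluster that holds wcH2B-8, 38 of 38 probe sets were lower, 31 of them unnamed, and in that of H2A-9, 14 of 14, 8 of them unnamed.

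The tests on histones, on Em and on splits of the arrays were chosen after the result was seen; those on probe sets of the same gene were not. Of the 18 histone H2A and H2B probe sets, 17 were lower at 13 °C. The median difference of the 18 came no closer to 0 than -4.98 under 5 normalizations and scalings. Both control scalings could only lower it (-5.67 and -5.50), and the others start from values that were already quantile normalized. The test therefore cannot decide on scaling of the arrays. The fall stands relative to the bulk of the array, whose median difference was 0.062. Loss of 5-prime signal of the size seen in the wheat control transcripts is argued against as the whole cause. Of the 18, which belong to 5 genes, 17 had a 95% interval wholly below -0.90, the largest such loss. That bound comes from glucose-6-phosphate dehydrogenase alone, whose gap widened by 0.62 to 1.16 with single arrays left out. A larger loss is not excluded, since 3 of the 7 gaps are limited by background and the position of the histone probes in their transcripts is not known here. Endosperm attached to the embryos would lower histones by diluting all embryo RNA. Of 1275 other probe sets as bright at 28 °C as the median histone probe set, 6.04% fell by 2.52 or more. The histone median was -5.04, so most equally bright probe sets did not share the histone fall. These values cannot decide on dilution, since quantile normalization removes a fall that bright probe sets have in common. Probe sets for transcripts that the other tissue also holds would not fall either. A lower share of dividing cells at 48 h after development at 13 °C stays open as a hypothesis and untested, since the cell cycle list had no named probe set.

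The 5 Em probe sets were higher at 13 °C. Their median difference stayed at 1.73 or more under the same 5 normalizations and scalings. Only the control scalings bear on scaling of the arrays here, since the others start from values that were already quantile normalized. The Em rise was larger than either control shift (0.63 and 0.46), which argues against a scaling difference of that size as the whole cause. Endosperm that holds its storage transcripts is argued against too: a rise from background would show, and all 12 markers had a 95% interval wholly below the median Em rise of 2.35, the highest upper limit being 0.70. Endosperm that had lost these transcripts, aleurone or other seed tissue remains open. Em transcripts kept longer after imbibition in seeds developed at 13 °C may be a biological reading, untested here.

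Probe sets of the same gene mostly agreed: among 113 genes with at least 2 probe sets past the threshold, the brightest 2 differed in sign for 7 (6.19%); 79 of the pairs come from the same cluster, where agreement is expected. Opposite pairs made up 11.8% of 34 pairs from different probe set clusters and 3.80% of 79 from the same cluster (Fisher's exact p = 0.195, two-sided), which leaves open whether clusters of different transcripts were joined under the same gene. The dimmer member of opposite pairs was lower at the median by 2.60 on the log2 scale (difference -2.60, permutation p = 0.042, two-sided), so disagreement went with lower signal. Most of these probe sets were not at background: only that of LOC543105 (3.88) lay below the highest unspiked control at 4.71. The others lay between 4.78 and 11.04, among them LOC100037594 at 7.70, TUBA at 10.66 and LOC543418 at 11.04.

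There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 20517 changed probe sets and 5685 at least 2-fold, and 1 of the 10 splits reached each count. The highest other split gave 0 of each in limma. Every other split puts arrays of both temperatures in each group, so the temperature difference enters the spread within groups. Low counts were therefore fixed in advance, and they cannot decide whether the real counts arose by chance. For the number of fixed lists past the threshold with the preset correlation, the real split gave 3 and the highest other split also 3, so 2 of the 10 reached it. Each of the other splits gave between 1 and 3 lists, though 0 probe sets passed in any of them. These splits keep part of the temperature difference, so their lists are not a rate of false calls. The other split with 3 lists set 13 °C arrays 1 and 3 and 28 °C array 3 against the rest.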
